A study of Rattus norvegicus with 16 samples.

How the data were processed

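RNA from rat neural stem cells in hydrogels was measured in 16 libraries, 2 in each of 8 groups that combine stiffness (100 Pa or 1.2 kPa), RGD (without or with) and time (12 h or 48 h). Per the labels' protocols, total RNA was extracted with a column kit and made into 3′ tag libraries, in which each transcript yields reads near its 3′ end, so that counts do not scale with transcript length.

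The deposited values are whole-number counts per transcript, with no normalization. Per the submitters' processing notes, FastQC, HISAT2 2.1.0, HTSeq and the rat build rn6 were used. The annotation release, the counting mode, the use of strand and the use of molecular identifiers are not given in the sources used here. Rows are versioned Ensembl transcripts, and how reads that fit several transcripts of a gene, or overlapping and antisense genes, were counted is not given either. Without known use of molecular identifiers, counting intervals cover counting error only. Every column could be matched to a sample by its title, and no row lacked a transcript identifier.

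A reference table of 47357 rat genes of assembly GRCr8 was searched for the identifiers. It lists an Ensembl identifier for 0 of its genes, and 0 identifiers of the count table could be matched to a symbol. The 33 gene lists fixed before the data were examined, covering signalling targets, lineage markers, matrix, stress and RNA quality, could therefore not be tested, and no genome coordinates are given.

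Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Transcripts were kept by edgeR's filter on expression by group (minimum count 10, minimum total 15), which left 7876 that held 99.6 to 99.7% of each library's counts. Libraries were scaled by TMM factors, which ranged from 0.893 to 1.176, and CPM values are normalised with them. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries with robust estimation, because 2 libraries per group are too few for a spread of their own. From it came 12 contrasts: stiffness averaged over all conditions, at each time and in each of the 4 conditions, its interactions with time and with RGD, RGD, time, and the interaction of RGD with time. Adjusted p-values are Benjamini-Hochberg values over the tested transcripts of a contrast, with a threshold of 0.05. Where a count of unadjusted p under 0.05 is set against chance, 394 is the number that uniform p-values would give. Some contrasts gave fewer, with 171 for stiffness by RGD and 251 for stiffness at 48 h without RGD. An excess over 394 is therefore not by itself evidence of a response. The SE given with a log2 fold change was derived from the quasi-likelihood test, as the size of the change over the square root of its F statistic. It is an approximation, and edgeR's test does not report it. Log2 CPM for principal components and positions used a prior count of 2. Nothing in the labels says that replicates were separate cultures, so that the p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise in each of the 8 groups (chi-square per degree of freedom 2.68 to 14.92), and none was treated as a duplicate. The common biological coefficient of variation was 0.174 over all libraries, 0.129 for those at 12 h and 0.207 for those at 48 h.

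The rule for named transcripts took those with the largest change in each direction among those with an adjusted p under 0.05, a mean of 20 or more counts over the libraries compared and the same sign in every matched condition. Its condition of a gene symbol could not be applied, and only the first 2 in each direction are named. For interactions, those with the smallest adjusted p are named. The 2 most abundant transcripts are described as part of the depth and were chosen after their values were seen.

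The fit was tested on simulated data with 7876 transcripts, of which 200 were changed in each of 5 draws. For stiffness over all conditions it recovered 53.7% of 1.5-fold and 84.8% of 2-fold changes. For stiffness at 12 h it recovered 17.6% of 1.5-fold and 58.2% of 2-fold changes, and for stiffness at 48 h 20.6% and 61.8%. For the interaction of stiffness with time it recovered 4.5% of 1.5-fold and 29.9% of 2-fold changes, and for stiffness at 12 h without RGD 3.3% and 26.3%. Between 4.4% and 7.0% of the calls were false. The simulation gave all groups the same spread, so that it does not cover the larger spread at 48 h.

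The alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 CPM in 2 libraries, no robust estimation, the replicate number as a block, a model without interactions, a fit of only the groups compared, and leaving out each library in turn. A fit without the 2 most abundant transcripts, libraries thinned at random to the lowest total, and correlations across transcripts with a mean of 100 or more counts were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.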

Results

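Adult rat hippocampal neural stem cells, the multipotent progenitors of the dentate gyrus that can form neurons and glia in culture, were grown inside hyaluronic acid hydrogels in a medium with 1 μM retinoic acid and 1% fetal bovine serum that allows mixed differentiation. The gels were either soft (100 Pa) or stiff (1.2 kPa). They either carried RGD, a short peptide to which integrin adhesion receptors bind, or did not, and RNA was taken at 12 h or 48 h. These 3 factors gave 8 groups of 2 libraries, 16 libraries in all, each made by sequencing tags at the 3′ ends of transcripts. The series was set up to find genes that depend on stiffness, so stiffness is the main comparison, and RGD and time are the other factors. Stiffness was tested averaged over conditions, at each time and within each condition. Within each of the 4 conditions, 2 libraries against 2, edgeR gave 0 calls in the main fit.

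The table of counts held 41078 transcripts, of which 15864 had at least 1 count in any library and 7876 had enough counts to be tested. Total counts per library ranged from 1829779 to 3420786, with a median of 2225930 at 12 h and 2691874 at 48 h. A library contained 10363 to 11385 transcripts with at least 1 count. A pair of transcripts took about as many counts as all others together. ENSRNOT00000069133.1 took 39.4% ± 2.12 of the counts at 12 h and 38.6% ± 1.28 at 48 h (SD, n = 8 each). ENSRNOT00000040038.3 took 12.2% ± 1.03 at 12 h and 10.9% ± 0.89 at 48 h (SD, n = 8 each). Without this pair the totals were 854022 to 1645978, which is the depth behind every other transcript. The sources used here do not pair the transcript identifiers with gene names, so transcripts are described as groups, and at most 2 that rose and 2 that fell are named by identifier for each comparison. Isoforms of a gene share reads, and the value of a single transcript is uncertain to that extent.

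Time separated the libraries most. The first principal component of log2 CPM held 42.6% of the variance and parted all 12 h libraries from all 48 h libraries. The second held 8.6%, and at 12 h it parted the 4 soft from the 4 stiff libraries.

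**Figure D1:**
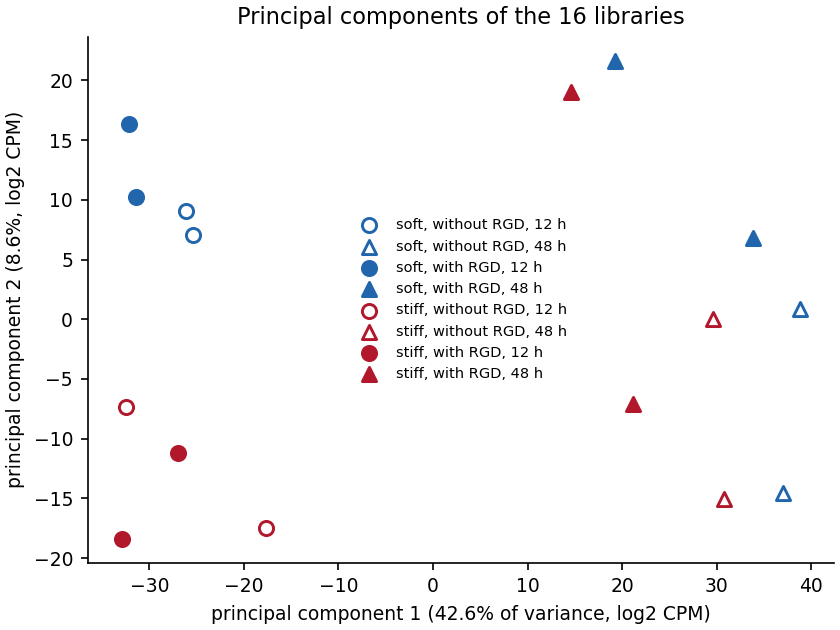
Scores of the 16 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with colour for stiffness, filled symbols for gels with RGD and triangles for 48 h. The 12 h libraries lie between -32.93 and -17.7 on the first component and the 48 h libraries between 14.65 and 38.8.

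At 12 h, stiff gels changed 59 of the 7876 transcripts, and 48 of these were higher in stiff gels and 11 lower. The 48 that were higher rose by a median log2 fold change of 0.96, or 0.93 without 1 transcript that had 3 or fewer counts in the soft libraries. The 11 that were lower had a median log2 fold change of -0.69. The largest rise by the rule for naming was that of ENSRNOT00000004279.5, from 10.3 ± 4.84 CPM in soft to 40.7 ± 17.1 CPM in stiff gels (SD, n = 4 each), with an edgeR log2 fold change of 1.99 ± 0.33 (SE) and an adjusted p of 0.00741. ENSRNOT00000066487.2 rose from 5.72 ± 2.0 to 18.5 ± 3.71 CPM (SD, n = 4 each; log2 1.69 ± 0.32, edgeR adjusted p = 0.0135). Among the transcripts that were lower, ENSRNOT00000033494.6 went from 13.5 ± 1.63 to 6.35 ± 3.68 CPM (SD, n = 4 each; log2 -1.25 ± 0.27, edgeR adjusted p = 0.0341). ENSRNOT00000007802.7 went from 54.8 ± 4.41 to 26.6 ± 9.29 CPM (SD, n = 4 each; log2 -1.03 ± 0.23, edgeR adjusted p = 0.0414). For all 4 of these transcripts, every stiff library at 12 h lay outside the range of the soft libraries. Depth moved with stiffness at this time: the 4 stiff libraries had 2294844 to 3420786 counts and 10857 to 11385 transcripts with at least 1 count, and the 4 soft libraries 1829779 to 2157015 counts and 10440 to 10828 transcripts. With all libraries thinned to the lowest total, the same test called 64 transcripts, 48 higher and 16 lower, and 48 of the 64 were among the 59.

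The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 stiff against 4 soft libraries, with the spread estimated over all 16 libraries. When the 12 h libraries were fitted alone, where the replicates were closer (a biological coefficient of variation of 0.129 against 0.174 over all libraries), 432 transcripts were called, 278 higher and 154 lower, and they contained all 59. The test without a filter on low counts called 204, which also contained all 59. DESeq2 called 101, among them 44 of the 59, and gave the other 15 no adjusted p. Limma-voom called 46, among them 41 of the 59. Without replicate 2 of the soft gel without RGD at 12 h, the 4 named transcripts had log2 fold changes of 1.798, 1.547, -1.295 and -1.026. In the full fit these were 1.99, 1.689, -1.245 and -1.029. The count of calls moved when single libraries were left out. This held also for 48 h libraries, which are outside this comparison but help set the shared spread. By edgeR it was 0 without replicate 2 of the soft gel without RGD at 12 h or replicate 1 of the stiff gel with RGD at 12 h, 1 without replicate 1 of the soft gel without RGD, and 6 and 4 without replicates 1 and 2 of the soft gel with RGD. It was 43, 25 higher and 18 lower, without replicate 2 of the stiff gel without RGD at 12 h, and 55, 54 higher and 1 lower, without its replicate 1. It was 38 and 36 without replicates 1 and 2 of the stiff gel without RGD at 48 h. It was 98 and 96 without those of the soft gel without RGD at 48 h, and 104 and 105 without those of the stiff gel with RGD at 48 h. At 12 h, the adjusted p of each of the 4 named transcripts rose above 0.05 when some 12 h libraries were left out, up to 0.109 for ENSRNOT00000004279.5, 0.137 for ENSRNOT00000066487.2, 0.219 for ENSRNOT00000033494.6 and 0.291 for ENSRNOT00000007802.7 (edgeR), and none of the 4 changed direction. The third of these was past the threshold under every other setting that gave it an adjusted p, as was the first (DESeq2 gave none for these and ENSRNOT00000066487.2), while the second missed it with limma-voom (adjusted p = 0.056) and the fourth when libraries were thinned to the lowest total (edgeR adjusted p = 0.0562).

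**Figure D2:**
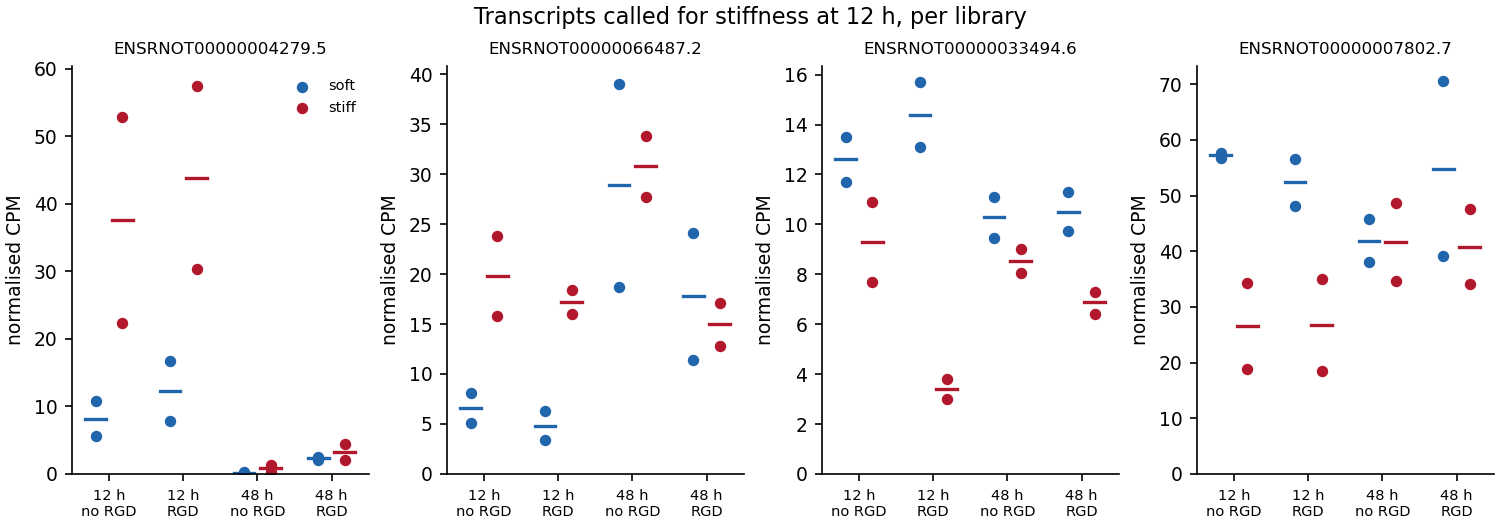
Normalised CPM of 4 transcripts called for stiffness at 12 h (y axis, 1 panel each) in gels without and with RGD at 12 h and 48 h (x axis), with 1 point per library, lines at the means of 2 libraries, and soft gels in blue and stiff gels in red. In ENSRNOT00000004279.5 the 4 stiff libraries at 12 h lie between 22.3 and 57.5 CPM and the 4 soft libraries between 5.62 and 16.8 CPM.

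At 12 h the fold changes between stiff and soft gels without RGD went together with those with RGD. Across the 2403 transcripts with a mean of 100 or more counts, the log2 fold changes in the gels without RGD and those with RGD, which come from separate libraries, had a Pearson correlation of 0.72. This is a correlation across transcripts, which are not independent replicates, and over all 7876 tested transcripts it was 0.32. Taken alone, neither condition, with 2 libraries against 2, gave a call by edgeR's adjusted p in the main fit. With no filter on low counts, edgeR called 24 in the gels without RGD and 62 in those with RGD. Without RGD, 450 transcripts had an unadjusted p under 0.05, where chance gives 394, and DESeq2 and limma-voom also called 0, while a fit of those 4 libraries alone called 46. With RGD, 666 had an unadjusted p under 0.05, DESeq2 called 13 and limma-voom 0, while a fit of those 4 libraries alone called 311. Leaving out 48 h libraries, which set the shared spread, gave up to 11 calls with RGD and up to 1 without, the former without replicate 1 of the soft gel without RGD at 48 h. The test of the difference between the stiffness effects with and without RGD, averaged over both times, called 0 transcripts by edgeR, DESeq2 and limma-voom, with 171 at an unadjusted p under 0.05.

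At 48 h no transcript passed edgeR's adjusted threshold for stiffness, with 577 at an unadjusted p under 0.05 and a smallest adjusted p of 0.137. DESeq2 called 1 and limma-voom 2. The edgeR test without a filter on low counts called 24, 22 higher and 2 lower. Leaving out replicate 1 of the soft gel without RGD at 48 h gave 66 calls, replicate 2 of the stiff gel with RGD at 48 h 9, and replicate 2 of the soft gel with RGD at 48 h 4. Replicate 2 of the soft gel without RGD at 48 h and either replicate of the stiff gel with RGD at 12 h gave 1 each, while a fit of the 48 h libraries alone gave 0. Taken alone, the gels without RGD gave 0 calls by edgeR, DESeq2 and limma-voom, with 251 at an unadjusted p under 0.05, and 15 calls without replicate 1 of the soft gel. The gels with RGD gave 0 by edgeR and limma-voom and 1 by DESeq2, with 409 at an unadjusted p under 0.05, and 8 calls without replicate 2 of the stiff gel. The log2 fold changes without and with RGD correlated across the 2403 abundant transcripts with r = 0.53, and over all 7876 tested transcripts with r = 0.16. Across the abundant transcripts r was 0.10 once replicate 2 of the soft gel without RGD at 48 h was left out. It was 0.21 once replicate 1 of the soft gel with RGD at 48 h was left out.

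Of the 59 transcripts called at 12 h, 44 had the same sign at 48 h. The 48 that were higher in stiff gels at 12 h had a median log2 fold change of 0.18 at 48 h, and the 11 that were lower had a median of -0.16. These transcripts were picked by their test at 12 h, which by itself inflates their 12 h values and so the gap to 48 h. Across the abundant transcripts, the stiffness fold changes at 12 h and 48 h correlated with r = 0.21, and with r = -0.049 without replicate 1 of the stiff gel with RGD at 48 h. The test of the difference between the stiffness effects at 12 h and 48 h called 0 transcripts by edgeR, DESeq2 and limma-voom, with 696 at an unadjusted p under 0.05 against 394 by chance, and it called 26 without replicate 1 of the soft gel without RGD at 48 h. The edgeR test without a filter on low counts called 32. By the main test, a difference between the times was therefore not shown for any single transcript.

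**Figure D3:**
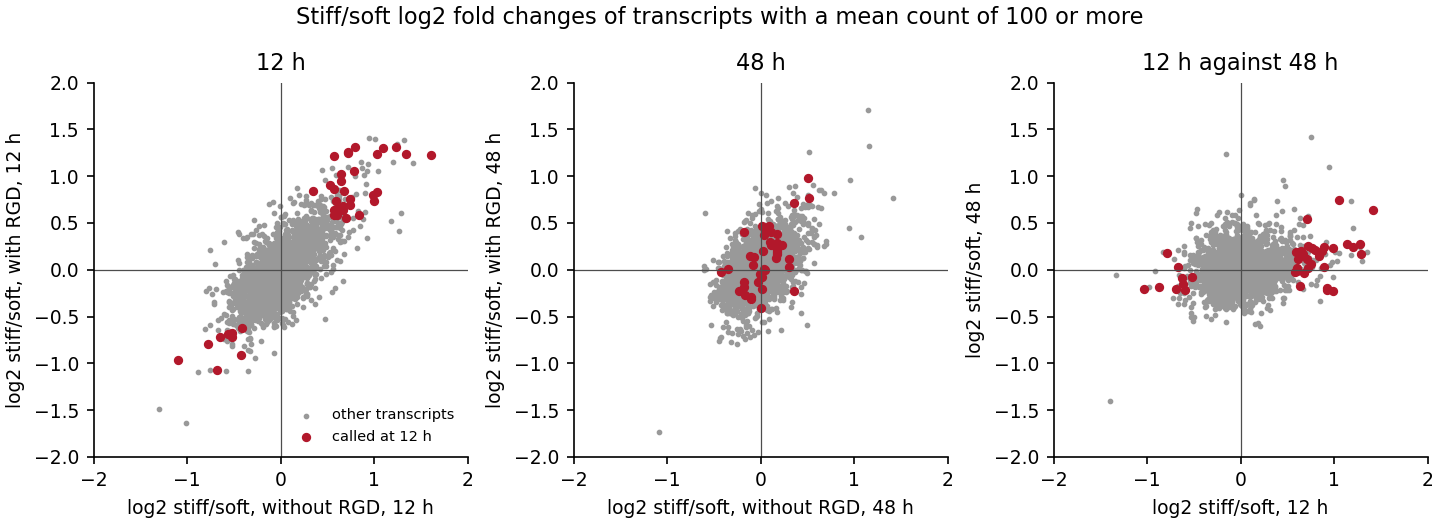
Log2 fold changes of stiff over soft gels for 2403 transcripts with a mean of 100 or more counts, without RGD (x axis) against with RGD (y axis) at 12 h and at 48 h, and 12 h (x axis) against 48 h (y axis) averaged over RGD. Red points are those called at 12 h, and the correlations are 0.72, 0.53 and 0.21.

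Averaged over all 4 combinations of RGD and time, 19 transcripts differed between stiff and soft gels, 17 higher and 2 lower in stiff gels, and 11 of them were also called at 12 h. ENSRNOT00000048525.3 was lower in stiff gels in each condition. Its level was 127 ± 88.8 CPM in soft and 49.7 ± 37.1 CPM in stiff gels (SD, n = 8 each; log2 -1.40 ± 0.22, edgeR adjusted p = 0.0198), with log2 fold changes of -1.39 ± 0.33 at 12 h and -1.41 ± 0.28 at 48 h (SE). ENSRNOT00000018367.5 fell from 22.3 ± 3.73 to 13.9 ± 2.26 CPM (SD, n = 8 each; log2 -0.69 ± 0.15, edgeR adjusted p = 0.036), and all 8 stiff libraries lay below the lowest soft library. ENSRNOT00000018637.6 rose from 11.7 ± 5.65 to 28.5 ± 16.1 CPM (SD, n = 8 each; log2 1.15 ± 0.18, edgeR adjusted p = 0.00362). Its log2 fold change was 1.56 ± 0.25 at 12 h and 0.74 ± 0.27 at 48 h (SE). ENSRNOT00000093582.1 rose from 6.30 ± 8.90 to 16.8 ± 13.5 CPM (SD, n = 8 each; edgeR adjusted p = 0.00826). Its fitted log2 fold change of 2.50 ± 0.41 rests in part on the soft libraries at 12 h, which had 0 or 1 count each. The fitted change was 3.69 ± 0.77 at 12 h and 1.31 ± 0.33 at 48 h (SE).

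This test set 8 libraries against 8, and its count depended on the tool and on single libraries. DESeq2 called 68, limma-voom 12, the model without interactions 36, among them 14 of the 19, and the test without a filter on low counts 150. Leaving out replicate 2 of the stiff gel with RGD at 48 h gave 222 calls, 118 higher and 104 lower, so that the excess of rises over falls depended on that library. Leaving out replicate 1 of the soft gel without RGD at 48 h gave 146, replicate 2 of the stiff gel without RGD at 12 h 44 (26 higher and 18 lower) and replicate 2 of the stiff gel with RGD at 12 h 29. Leaving out replicate 1 or 2 of the soft gel without RGD at 12 h gave 8 or 4 calls, and for the soft gel with RGD at 12 h 10 or 6. Leaving out replicate 1 of the stiff gel with RGD gave 7 calls at 12 h and 4 at 48 h. The call of ENSRNOT00000018367.5 was lost in 12 of the 16 fits that left out a library (adjusted p up to 0.121, edgeR) and with limma-voom (adjusted p = 0.0529). That of ENSRNOT00000048525.3 was lost in 7 (up to 0.117, edgeR), and that of ENSRNOT00000093582.1 in 1 (0.0527, edgeR), with limma-voom (adjusted p = 0.0566) and without interactions (edgeR adjusted p = 0.062). ENSRNOT00000018637.6 was past the threshold in all of them.

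RGD, averaged over stiffness and time, gave no call by edgeR or limma-voom. By edgeR 898 transcripts had an unadjusted p under 0.05, against 394 if p-values were uniform, and the smallest adjusted p was 0.121. DESeq2 called 10, 5 higher and 5 lower with RGD, and the test without a filter on low counts called 83. By edgeR, 11 calls appeared without replicate 1 of the soft gel without RGD at 48 h or of the stiff gel without RGD at 12 h, and 7 without replicate 1 of the soft gel with RGD at 48 h. There were 5 and 1 without replicates 2 and 1 of the stiff gel with RGD at 48 h, and 4 without replicate 2 of the soft or of the stiff gel without RGD at 48 h. The difference between the RGD effects at 48 h and 12 h passed for 1 transcript by edgeR, DESeq2 and limma-voom. ENSRNOT00000020505.3 stood at 45.7 ± 13.3 CPM in soft and 45.4 ± 6.84 CPM in stiff gels without RGD at 48 h, and at 94.8 ± 10.7 and 114 ± 21.3 CPM with RGD (SD, n = 2 each). At 12 h the levels were 74.5 ± 9.28 and 72.6 ± 1.36 CPM without RGD, and 64.2 ± 1.23 and 60.3 ± 0.739 CPM with RGD (SD, n = 2 each). The difference was 1.42 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 0.00511), and its adjusted p was 0.0613 without replicate 1 of the soft gel without RGD at 12 h.

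Between 12 h and 48 h, 3049 transcripts changed, 38.7% of those tested, with 1506 higher and 1543 lower at 48 h. Of these, 847 changed more than 2-fold, 339 upward and 508 downward, and 210 changed more than 4-fold. ENSRNOT00000018581.4 had 1 count over all 8 libraries at 12 h and 548 counts over the 8 libraries at 48 h, a ratio of 511 with a 95% counting interval of 91.3 to 20200 after scaling for library size (edgeR adjusted p = 9.08e-05). ENSRNOT00000001490.6 rose from 1.38 ± 0.442 to 17.7 ± 4.26 CPM (SD, n = 8 each; log2 3.67 ± 0.26, edgeR adjusted p = 1.72e-11). ENSRNOT00000022549.4 fell from 33.5 ± 8.86 to 0.461 ± 0.607 CPM (SD, n = 8 each; log2 -6.78 ± 0.34, edgeR adjusted p = 4.64e-14). ENSRNOT00000010975.5 fell from 17.5 ± 3.52 to 0.65 ± 0.44 CPM (SD, n = 8 each; log2 -4.65 ± 0.30, edgeR adjusted p = 2.76e-12). For each of these 4, the 8 libraries of one time lay outside the range of those of the other. The count stayed between 2655 and 3102 under every alternative and with each library left out.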

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

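ENSRNOT00000020505.3 differed between times in its response to RGD, which was tested as an interaction. The effect of RGD at 48 h was higher than that at 12 h by 1.42 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 0.00511), with all 4 libraries with RGD above all 4 without RGD at 48 h and below all 4 at 12 h. It was the only transcript called in any of the 3 interactions tested. Of 100 arrangements of the RGD labels within stiffness and time, drawn from 648 and including the real one, 21 gave at least 1 call for this interaction and the highest other gave 43, so that chance cannot be excluded for the count of 1. The arrangement with 43 reversed the RGD labels of the soft gels at 12 h and kept those of the stiff gels at 48 h, so that part of its calls can be the RGD difference itself read as an interaction. No explanation was tested for this transcript.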

How the results depend on the processing

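The fits without the 2 most abundant transcripts and with libraries thinned to the lowest total were chosen after seeing the data. The count for time stayed within 1.5 times its value of 3049 under all 10 alternatives and with each library left out, and stiffness by RGD stayed at 0. For the other counts, the cause of a change was not tested except where given. Without a filter on low counts, calls numbered 150 for stiffness over all conditions, 204 at 12 h, 24 at 48 h, 24 at 12 h without RGD, 62 at 12 h with RGD, 2 at 48 h without RGD, 7 at 48 h with RGD, 32 for stiffness by time, 83 for RGD and 7 for RGD by time. DESeq2 gave 68 for stiffness over all conditions, 101 at 12 h, 1 at 48 h, 13 at 12 h with RGD, 1 at 48 h with RGD and 10 for RGD. Limma-voom gave 12 for stiffness over all conditions and 2 at 48 h, the latter also the count without robust estimation, and the model without interactions gave 36 over all conditions. A fit of only the groups compared gave 432 at 12 h, 46 without RGD and 311 with RGD; it estimates the spread from the 12 h libraries, which were closer to each other. Thinned libraries gave 3 calls for RGD. The named transcripts kept their direction under every alternative that gave them an adjusted p. DESeq2 gave none for ENSRNOT00000004279.5, ENSRNOT00000066487.2 and ENSRNOT00000033494.6. DESeq2 can leave out transcripts of low mean count, and whether that was the reason here was not checked.

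The replicate numbers were not taken to pair the samples, since not every pair of groups agreed: deviations of same-numbered libraries correlated between -0.22 and 0.19 over 28 pairs of groups, with a median of 0.003 and 5 over 0.1. Among the 5 were soft and stiff gels at 48 h without RGD (0.14) and with RGD (0.19). With the replicate block, calls were 57 for stiffness over all conditions and 95 at 12 h, and no other count moved by over 1.5 times. Stiffness at 48 h stayed at 0. The block gives replicate 2 the same shift in every group. At 48 h, same-numbered deviations of the soft gels without and with RGD ran opposite (-0.22). A pairing within each RGD condition was therefore not modelled, and the 0 at 48 h is not shown to hold under it.

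With each library left out in turn, where the lone sample of that group is assumed to vary like the other groups, counts ranged from 4 to 222 for stiffness over all conditions, 0 to 105 at 12 h, 0 to 66 at 48 h, 0 to 1 at 12 h without RGD, 0 to 11 at 12 h with RGD, 0 to 15 at 48 h without RGD, 0 to 8 at 48 h with RGD, 0 to 26 for stiffness by time, 0 to 11 for RGD, 2655 to 3102 for time and 0 to 3 for RGD by time. Several of the highest came without replicate 1 of the soft gel without RGD at 48 h, whose group had the widest spread (0.254). The correlation of stiffness fold changes at 12 h and 48 h turned to -0.049 without replicate 1 of the stiff gel with RGD at 48 h and was highest, at 0.378, without replicate 2. Tests of gene lists, their estimated correlation, rotation test and replicate block were not run, since identifiers were not paired with names. At this depth and replication, the simulated test of stiffness at 12 h recovered 58.2% of 2-fold and 17.6% of 1.5-fold changes, so that smaller changes were mostly not detectable.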

Other observations

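The tests of fewer counts at 48 h, of a larger spread at 48 h, of a response that differs between the times and of the order of libraries on the time axis were chosen after their results, or closely related ones, were seen; the other tests were written down before their results.

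Stiff and soft gels at 12 h differed in overlapping transcripts without and with RGD, which was measured by picking transcripts in one RGD condition and reading them in the separate libraries of the other. The 100 transcripts with the smallest p for stiffness at 12 h without RGD, 76 of them higher in stiff gels, were read in the gels with RGD. There 98 of the 100 moved the same way at 12 h, with a median of 0.63 on the log2 scale in the direction of the pick. In the other direction, 90 of 100 moved the same way with a median of 0.53. At 48 h the same picks gave 71 and 69 of 100 with medians of 0.18 and 0.08. Picks made at 48 h gave smaller medians: 72 and 80 of 100 moved the same way in the other RGD condition at 48 h, with medians of 0.25 and 0.27. At 12 h 56 and 61 did, with medians of 0.06 and 0.06. The agreement at 48 h has a limit. The correlation of fold changes without and with RGD at 48 h was 0.53, and an arrangement with other stiffness labels reached 0.50.

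The pattern weighed first is that stiffness gave 59 calls at 12 h and 0 at 48 h. Fewer counts do not explain it, since the median total was 2691874 counts at 48 h and 2225930 at 12 h. The spread between replicates was larger at 48 h (0.207 against 0.129). That it hides the response seen at 12 h, still present at the same size, is argued against by single pairs of a stiff and a soft library. Among transcripts picked at 12 h in the other RGD condition, the highest such library pair at 48 h gave a median of 0.39 with RGD and 0.21 without. The lowest at 12 h gave 0.47 and 0.45. That the spread hides a response in other transcripts at 48 h stays open. The soft gel without RGD at 48 h had the widest spread (0.254), and leaving out its replicate 1 gave 66 calls at 48 h, 4 of them among the 59, against 98 at 12 h, while leaving out its replicate 2 gave 1 and 96. For the transcripts picked at 12 h, these library pairs put the stiff-soft difference at 48 h below that at 12 h, for a cause not told apart. Across the abundant transcripts, a stiffness response that differs between 12 h and 48 h stays open. Correlations of fold changes between separate libraries were 0.72 at 12 h and 0.53 at 48 h, and across times 0.22 and 0.10 with the RGD condition also changed, 0.29 with RGD and 0.02 without, but the 48 h value was 0.099 without replicate 2 of the soft gel without RGD and 0.21 without replicate 1 of the soft gel with RGD. The interaction test called 0 transcripts, or 32 without a filter on low counts. Gels of one time may share a day of casting or harvest that the labels do not give. A pairing of soft and stiff gels by replicate number within each RGD condition at 48 h was not modelled and stays open too.

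The other arrangements of the libraries bear on these counts. With stiffness labels exchanged within RGD, the 12 h libraries can be arranged in 18 ways, too few for a share under 0.05. The real one gave 59 calls and the highest of the others 0, and in fits of the 12 h libraries alone 432 and 0; in each case 1 of 18 reached the real count. For stiffness at 48 h the real count of 0 is reached by all 18 whatever the data, so that the tally says nothing; the highest other gave 77, by setting replicate 2 without RGD and replicate 1 with RGD, soft and stiff alike, against the rest. This arrangement follows the replicate number within each RGD condition. Same-numbered deviations of soft and stiff gels at 48 h correlated at 0.14 without RGD and 0.19 with RGD. Those of the soft gels without and with RGD correlated at -0.22. The test counts such a pairing of soft and stiff gels as spread, and it was not modelled. The correlation between the fold changes without and with RGD was 0.72 at 12 h, with 0.35 the highest among the other arrangements, and 0.53 at 48 h, with 0.50 the highest other. For stiffness over all conditions, 2 of 100 arrangements drawn from 648 gave at least 19 calls, the real one included. The highest other gave 20, more than the real one. That share is under 0.05 among those drawn, and the rest of the 648 were not run. For time, 1 of 100 reached 3049 and the highest other gave 1988, also a share under 0.05. Both tallies exchange libraries, which may be technical replicates, so that chance differences between gels or cultures are not excluded. For stiffness by time, stiffness by RGD and RGD the real count was 0, which all 100 arrangements reach whatever the data, so that these tallies say nothing about chance. The highest others gave 174, 115 and 28 calls. The arrangement with 174 kept the stiffness labels at 12 h and reversed them with RGD at 48 h. That with 115 kept them without RGD and reversed them with RGD at 12 h. In both, part of the calls can be the stiffness difference itself read as an interaction. Both also set replicate 2 of the soft and stiff gels together at 48 h, without RGD for 174 and with RGD for 115. The shares of these were not separated.

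The pattern weighed second is the place of the libraries with RGD on the axis from the mean 12 h library (0%) to the mean 48 h library (100%). At 48 h they lay at 91.6% ± 12.0 with RGD and 108.4% ± 6.5 without (SD, n = 4 each; exact two-sided permutation p = 0.0556, the smallest this design allows). At 12 h they lay at -4.2% ± 4.0 and 4.2% ± 9.2 (SD, n = 4 each; exact p = 0.167). Over both times the difference was -12.6 percentage points, with an exact two-sided permutation p of 0.00772 with labels exchanged within stiffness and time (0.0463 adjusted over 6 such tests). With each library left out of the means it was -9.8 to -15.4, nearest to 0 without replicate 2 of the stiff gel without RGD at 12 h. The axis itself was still that of all 16 libraries. The order of the libraries had been seen before this test was chosen, so its p-value cannot exclude a chance order. Depth and a few abundant transcripts are argued against: the difference was -13.1 with every library thinned to the lowest total and -12.6 without the 100 most abundant transcripts. A slower passage along the time course with RGD may account for the difference, as a hypothesis that was not tested. A difference in the hours of handling between gels, which the labels do not give, stays open. The design cannot tell these apart. For stiffness the difference was -5.4 percentage points over both times (exact permutation p = 0.218). With each library left out of the means, on the same axis, it was -2.6 to -8.2, nearest to 0 without replicate 1 of the stiff gel without RGD at 12 h. With all libraries the difference was 1.4 at 12 h (exact permutation p = 0.944) and -12.1 at 48 h (exact permutation p = 0.111).

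The last pattern weighed is replicate 2 of the stiff gel without RGD at 12 h, which lay at 15.8% on that axis, above the other 12 h libraries. RNA of 48 h cells mixed in cannot be told apart from a library further along the time course. The 38 transcripts at least 4-fold higher at 48 h would need a share of 7.5% of foreign RNA, which predicts a median log2 shift of -0.09 in the 66 transcripts at least 4-fold lower at 48 h. A library at its place on the axis predicts -0.42. The observed median was -0.22, and the medians of the 7 other 12 h libraries had an SD of 0.17, so that both predictions lie within 2 SD of it. No biological explanation was tested, since its group has 1 other library.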
